A study of Mus musculus with 8 samples.

How the data were processed

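RNA was measured in spleens of female C57BL/6 mice, wild type (WT) or lacking the microRNA miR-155 (KO), without infection or 6 days after infection with Plasmodium berghei ANKA, a rodent malaria parasite. The labels describe 8 libraries, 2 in each of 4 groups, all with an age of 8 weeks. The sample titles and the table's columns mark the infected groups with a 2, whose meaning is not given, while the source labels and the series' design text give day 6, which is used here. Per the labels' protocols, polyadenylated RNA was isolated from total RNA and fragmented, and the second cDNA strand was made with dUTP and removed enzymatically, which keeps the strand of the transcript. The submitters' processing notes name CASAVA, TopHat and Cuffdiff, without versions, and the mouse genome build mm9. The annotation, filters, settings and scaling between libraries are not given in the sources used here.

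The deposited table holds FPKM values (fragments mapped to a transcript, scaled to its length in kilobases and to the mapped fragments of the library), per the file headers, with 1 column for each of the 4 groups. There is no value per library. How the authors combined the 2 libraries of a group is not given in the sources used here, and each value is therefore the authors' value for a group, with no SD and no n. Rows are 53386 identifiers of the form used for UCSC known genes, which label single transcripts, so that reads of 1 gene can be divided among several rows. The table gives no gene symbols, positions or lengths. None of the 53386 identifiers occurred in the 5 reference tables of gene names and cross-references that were searched, which follow a later mouse assembly than mm9, and the number matched to a gene name was 0. Transcripts are therefore named only by the identifiers in the table, and no coordinates are given. The depth behind the values is unknown, so no counting interval or detection limit is given. An exact 0 can be a failed estimate and is reported as listed at 0.

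The design fixed before the data were examined had called for 6 comparisons with limma on log2(FPKM + 0.5), 25 gene lists with 443 entries, a search for miR-155 sites in 3′ untranslated regions and the miR-155 host gene. The tests need values per library and the gene lists, host gene and site search need gene names, so these were not analysed here. The same design stated what to do with 1 value per group: no test, and a ranking of transcripts by the ratio of (FPKM + 0.5) among those with at least 5 FPKM in a group. This was done for 11750 transcripts, 22.0% of the table, that reached 5 FPKM in at least 1 of the 4 groups. For each, log2 ratios were computed for infection in WT, infection in KO, KO against WT without infection and KO against WT in infection, together with the difference of the infection responses and the mean of both genotype differences. A pseudocount of 0.5 FPKM was added to each value, which understates ratios of low transcripts. Transcripts were counted as different at a ratio of at least 2-fold (1 on the log2 scale). That limit is a rule of size, not of significance, since nothing in the table measures the spread between animals. For the same reason no p-value is given.

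The infection ratios in WT and KO share no column of the table, nor do the genotype ratios in uninfected and infected spleen. Their agreement was summarised by Pearson's r and Spearman's rho across transcripts, which are not independent replicates. The transcripts that differed in both were also counted. That count was set beside the number that independent lists would share (the product of both list sizes divided by 11750). The product takes every transcript as equally likely to pass 2-fold, so an excess over it alone does not show shared differences. The example transcripts are the 2 highest and 2 lowest by ratio for infection in WT, among those above 0 in both groups and at 5 FPKM or more in one of them. Transcripts listed at 0 in a group were not ranked, a restriction added after the values were seen, and identifiers without gene names were limited to these 4 and the most abundant transcript, chosen after its values were seen.

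The calculation was tested on simulated data for infection in WT with 11133 transcripts. Of 200 transcripts given a 4-fold change against noise with an SD of 0.4 on the log2 scale, 199 met the filter, and 96.0% of these passed 2-fold in the right direction. Of the unchanged transcripts 6.43% also passed, and r between the simulated infection responses of unchanged transcripts was -0.01. The SD was chosen, not measured, and the noise was independent and equally wide at all levels. Both values follow from that setting and give no background rate for the real counts. Alternatives covered the pseudocount, the filter on low values and the scaling of the columns. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.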

Results

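Spleen RNA profiles were compared between wild-type mice and mice lacking miR-155, a microRNA expressed in activated immune cells, before and during blood infection with Plasmodium berghei ANKA. The 4 groups were uninfected WT, uninfected KO, WT at day 6 and KO at day 6 of infection, with 2 libraries in each according to the labels. The authors' table gives 1 FPKM value per group and transcript. The values below therefore carry no replicate error, and differences are described by size without a test.

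Between 17024 and 17627 transcripts reached 1 FPKM in a group. The number was 17249 in uninfected WT, 17024 in uninfected KO, 17627 in infected WT and 17443 in infected KO. Another 32633 of the 53386 transcripts stayed under 1 FPKM in all 4 groups, and 12926 of these were listed at 0 throughout. The most abundant transcript, uc012ath.1, had 85321 FPKM in uninfected WT, 98096 in uninfected KO, 272945 in infected WT and 101888 in infected KO. It made up 13.2%, 12.2%, 31.8% and 15.2% of the summed FPKM of these groups. Its ratio of infected to uninfected was 3.20 in WT and 1.04 in KO as deposited, and 2.41 and 1.24 when each column was rescaled to the same total. That total includes the transcript itself. With it left out of the total the ratios were 3.07 and 1.29, and under median-ratio scaling 2.95 and 0.94. Quantile normalization, which gives equal ranks equal values, set both to 1. The direction in KO thus depended on the scaling. The summed FPKM itself ranged from 646344 in uninfected WT to 857295 in infected WT. Much of this range is uc012ath.1 itself, with 85321 and 272945 FPKM in these groups. Rescaling to a fixed total therefore shifts the ratios of all other transcripts with the level of uc012ath.1.

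The first comparison asked how the wild-type spleen differed at day 6 of infection. Of the 11750 transcripts compared, 1612 were at least 2-fold higher and 1189 at least 2-fold lower in infected than in uninfected WT spleen, together 23.8%. The differences reached 4-fold for 451 higher and 421 lower transcripts. The middle 90% of log2 ratios ran from -1.61 to 1.77. Among transcripts above 0 in both groups, the highest ratios belonged to uc009fgq.1, with 0.329 FPKM in uninfected and 68.2 FPKM in infected WT, and uc009gqc.1, with 0.00141 and 29.5 FPKM. In KO spleen uc009fgq.1 also stood far higher in infection, at 0.457 FPKM uninfected and 81.0 FPKM infected, a log2 ratio of 6.41 against 6.37 in WT on the (FPKM + 0.5) scale. The transcript uc009gqc.1 was listed at 0 in uninfected KO and had 0.67 FPKM in infected KO. The lowest ratios belonged to uc007lrp.2, with 455 FPKM in uninfected and 0.00766 FPKM in infected WT, and uc009cdo.1, with 94.2 and 0.177 FPKM. Both were listed at 0 in uninfected KO and had 0.345 and 0.0565 FPKM in infected KO, so they were high only in uninfected WT. In each of these examples the lower WT value was under the pseudocount of 0.5 FPKM, so the size of the ratio depended on it. The median log2 ratio over all compared transcripts was 0.11. On columns rescaled to a fixed total the median was -0.28 and the counts became 961 higher and 2115 lower. At a fixed total without the most abundant transcript the median was 0.05, with 1525 higher and 1312 lower. The balance of higher and lower transcripts thus depended on the scaling, and on whether that transcript was counted in the total.

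The second comparison asked the same question in spleens without miR-155. Infected KO spleen had 1199 transcripts at least 2-fold higher and 1500 at least 2-fold lower than uninfected KO spleen, together 23.0% of those compared. At 4-fold the numbers were 299 and 586. The middle 90% of log2 ratios ran from -1.998 to 1.47, with a median of -0.01. Rescaling to a fixed total moved the median to 0.24 and turned the counts to 1841 higher and 1160 lower.

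**Figure D1:**
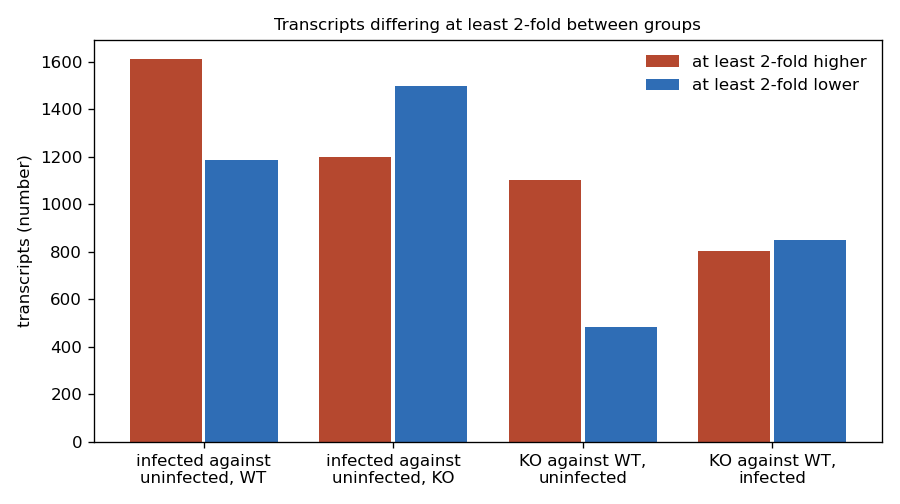
Number of transcripts (vertical axis) at least 2-fold higher (red) or lower (blue) in each of the 4 comparisons between groups, of 11750 compared, from FPKM as deposited with a pseudocount of 0.5. Infected and uninfected spleen differed in 2801 transcripts in WT and 2699 in KO. KO and WT differed in 1588 without infection and 1654 in infection. There are no error bars because each group has 1 value.

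The infection responses of the 2 genotypes overlapped. A handling difference between uninfected and infected spleens would enter both responses, and the labels give no batch. Across the 11750 transcripts, the log2 ratios in WT and KO correlated with r = 0.45 and rho = 0.39. There were 565 transcripts at least 2-fold higher in both genotypes, where independent lists would share 164, and 534 at least 2-fold lower in both, where independent lists would share 152. In the opposite sense, 114 transcripts were higher in WT and lower in KO, and 82 were lower in WT and higher in KO. Independent lists would share 206 and 121. Of the transcripts that passed 2-fold in both genotypes, 84.9% thus had the same direction. Agreement was closest among the most abundant transcripts. Abundance here and below is the geometric mean of (FPKM + 0.5) over the 4 groups, which is above 0 even where a group is listed at 0. At a geometric mean of 1000 FPKM or more, r was 0.77 over 78 transcripts. From 100 to 1000 FPKM it was 0.31 over 612 transcripts, or 0.63 without the 6 that were listed at 0 in some group.

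**Figure D2:**
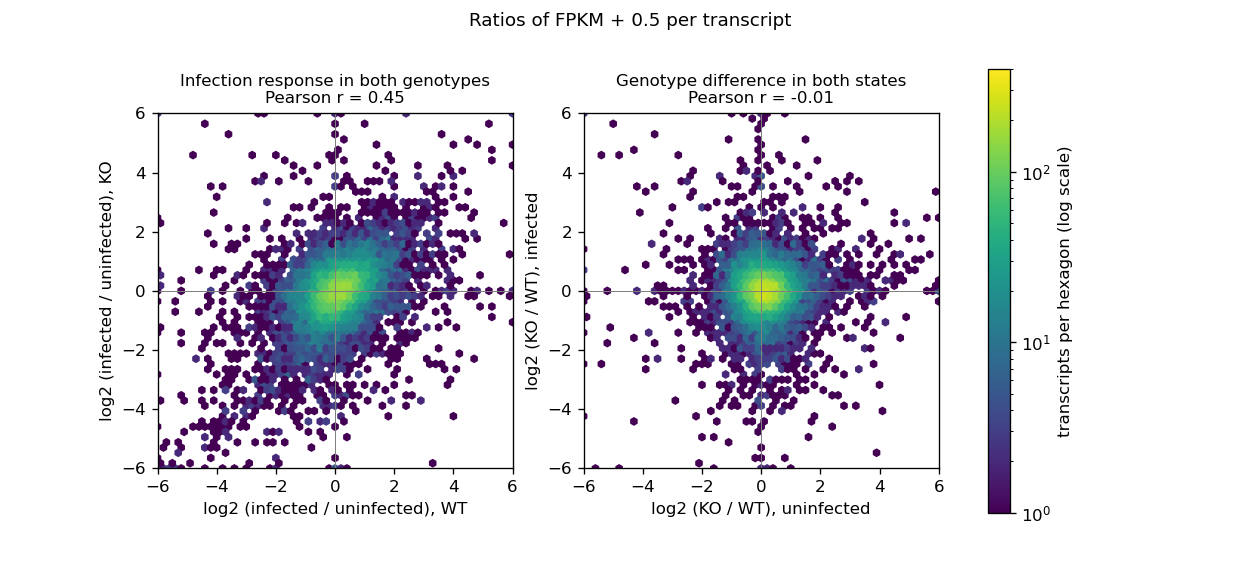
Each hexagon is coloured by the number of transcripts (log colour scale) at its log2 ratios of FPKM + 0.5; ratios beyond 6 in either direction are drawn at the edge. Left, infected over uninfected in WT (horizontal) and KO (vertical), r = 0.45; right, KO over WT in uninfected (horizontal) and infected spleen (vertical), r = -0.01. The left cloud is tilted along the diagonal and the right one is not.

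The next comparisons asked how KO spleen differed from WT spleen, first without infection and then in infection. Without infection 1102 transcripts were at least 2-fold higher and 486 at least 2-fold lower in KO than in WT, 13.5% of those compared, and the median log2 ratio was 0.14. In infection 802 were higher and 852 lower, 14.1% of those compared, with a median of 0.00233. After rescaling to a fixed total the counts were 693 higher and 985 lower without infection, and 1583 higher and 566 lower in infection. With the most abundant transcript left out of the total they were 688 and 1046 without infection, and 918 and 848 in infection. Among the compared transcripts, low ones passed 2-fold most often, but the filter itself favours this. A transcript with a geometric mean under 5 FPKM was kept only if some group reached 5 FPKM, so its groups had to differ. The shares under 5 FPKM therefore do not describe low transcripts in general. Among those with a geometric mean under 5 FPKM, 30.9% passed 2-fold between the genotypes without infection and 35.5% in infection. From 20 to 100 FPKM the shares were 7.74% and 6.40%. Infected and uninfected WT differed at least 2-fold in 51.3% of the compared transcripts under 5 FPKM, where the same filter raises the share. From 20 to 100 FPKM they differed in 16.3%.

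The genotype differences of uninfected and infected spleen were uncorrelated across transcripts. Their log2 ratios had r = -0.01 and rho = 1.3e-06 across the 11750 transcripts. There were 156 transcripts higher and 99 lower in KO in both states, and 218 that passed 2-fold in both states in opposite directions. The share with the same direction was 53.9%. Every one of the 4 direction pairs held more transcripts than independent lists would share. Those numbers were 75.2 higher in both, 35.2 lower in both, and 79.9 and 33.2 in opposite directions. They take every transcript as equally likely to pass 2-fold, while low compared transcripts passed most often. The excess is therefore not read as recurring genotype differences. From 100 to 1000 FPKM rho was -0.01 and r was 0.04 over 612 transcripts, and r was 0.12 without the 6 listed at 0 in some group. The 78 transcripts at 1000 FPKM or more differed from the rest, with r = 0.44 and rho = 0.46, although none of them passed 2-fold in the same direction in both states.

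The last 2 comparisons combined all 4 groups. The infection response of KO exceeded that of WT by at least 2-fold for 1226 transcripts and fell short of it by at least 2-fold for 1856, with a median difference of -0.18 on the log2 scale. This balance turned with the scaling, to 2987 and 861 at a fixed total with a median of 0.46, to 2029 and 1195 at a fixed total without the most abundant transcript, and to 1487 and 1473 under quantile normalization. Averaged over both states, 541 transcripts were at least 2-fold higher and 368 at least 2-fold lower in KO. At a fixed total without the most abundant transcript these were 471 and 517. To set these on one scale, the 4 groups were divided into pairs in the 3 possible ways and the mean log2 values of the pairs were subtracted. Infected minus uninfected had an SD of 1.05 across transcripts and put 2140 transcripts past 2-fold. KO minus WT had an SD of 0.64 and put 909 past 2-fold. The crossed division, in which each pair held 1 WT and 1 KO and 1 infected and 1 uninfected group, had an SD of 0.64 and put 906 past 2-fold. The like widths of the last 2 follow from the near-zero correlation of the genotype differences and add nothing to it. Without values per library, none of the 3 could be set against the spread between animals.

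Some transcripts were abundant in part of the groups and listed at 0 in others. Among 2745 transcripts that had at least 20 FPKM in every group where they were above 0, 2700 were above 0 in all 4 groups. Listed at 0 in both infected groups alone were 16, and in both uninfected groups alone 2. None was listed at 0 in both WT groups alone or in both KO groups alone, and 3 were at 0 in uninfected KO and infected WT together. Above 0 in a single group were 5 transcripts in uninfected KO, 3 in infected WT and 2 in infected KO. Single groups were at 0 for 2 transcripts in uninfected WT, 5 in uninfected KO, 3 in infected WT and 4 in infected KO. The 16 had between 20.8 and 2314 FPKM in the uninfected groups, with medians of 684 in WT and 689 in KO.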

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

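All tests in this part were chosen after the values had been seen, except the one on the balance of higher and lower transcripts, whose prediction was written before its result was computed.

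There were 196 transcripts at least 2-fold higher with infection in one genotype and at least 2-fold lower in the other. This difference between the genotypes was not tested, since each group has 1 value. Over the other settings the number ranged from 150 without the transcripts listed at 0 in any group to 414 with no filter on low values, and it was 389 with a mean of at least 0.5 FPKM and 267 at a fixed total.

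The genotype differences of uninfected and infected spleen were uncorrelated over all compared transcripts. In both states 156 transcripts were higher and 99 lower in KO, while 218 passed 2-fold in opposite directions. Noise confined to transcripts under 100 FPKM would leave agreement above that level, but only if genotype effects there were shared by both states. Among the 612 transcripts from 100 to 1000 FPKM rho was -0.0065, while r was 0.04, or 0.12 without the 6 transcripts listed at 0 in some group. The lack of correlation was thus not limited to transcripts under 100 FPKM. Whether shared effects exist is unknown, so these values cannot decide on noise as a cause. At 1000 FPKM or more rho was 0.46 over 78 transcripts, but no transcript there passed 2-fold in the same direction in both states: 3 were higher and 0 lower in KO without infection, and 0 higher and 5 lower in infection. Whether noise in transcripts under 1000 FPKM accounts for part of the pattern therefore stays open. Genotype effects that depend on infection, and chance differences between the 2 libraries of each group, stay open as untested, because no spread between libraries is at hand.

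The 16 transcripts at 20 FPKM or more in both uninfected groups and at 0 in both infected groups stood against 2 with the reverse pattern. If estimates had failed independently in each group, with the same chance for every transcript, 0.13 among 3182 would have been at 0 in both infected groups. This argues against failures of that kind only. Failed estimates that recur at the same transcripts in both infected groups were not tested and stay open. Infection itself and a handling difference between uninfected and infected spleens cannot be told apart, since the labels give no batch and every infected group is on one side.

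As deposited, more transcripts were higher than lower with infection in WT, and more were lower than higher in KO. The KO balance shares the uninfected KO column with the genotype comparison without infection, where 1102 were higher and 486 lower in KO. The difference of the infection responses uses that column too. These balances are therefore not separate findings. A difference in scale between the columns is a candidate explanation. Median-ratio scaling took its factors from all transcripts above 0 in every group, also those under 5 FPKM. Among the compared transcripts it moved the median log2 ratio from 0.11 to -0.00019 in WT and from -0.01 to -0.14 in KO. The share of higher transcripts moved from 57.6% to 50.4% in WT and from 44.4% to 35.8% in KO. The KO share was under the bound of 45% that was written beforehand to exclude the explanation. That bound was wrong, because the deposited KO share already met it and a factor common to all transcripts sets the share by itself. Rescaling to a fixed total gave 31.2% in WT and 61.3% in KO. The same without the most abundant transcript gave 53.8% in WT and 64.4% in KO, and quantile normalization 51.2% and 48.8%. Scale and biology cannot be told apart, since nothing in the table says which scaling is right.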

How the results depend on the processing

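Of 140 values under other settings, 116 stayed close to the reported ones (counts within 1.5 times, r within 0.1, shares within 10 percentage points and on the same side of 50%). The correlation of infection responses ranged from 0.37 to 0.48 and that of genotype differences from -0.02 to 0.02. The share with the same direction among transcripts past 2-fold in both ranged from 80.8% to 86.7% for infection and from 48.8% to 54.2% for genotype. Counts grew where more low transcripts were let in. With no filter on low values (40460 transcripts) they were 5621 for infection in WT, 5385 for infection in KO, 3206 and 3756 for genotype without and in infection, 6940 for the difference of responses and 1672 for genotype over both states. With a mean of at least 0.5 FPKM (21444 transcripts), chosen after seeing the data, they were 4974, 4761, 2820, 3209, 5817 and 1572 in the same order. The share of higher transcripts turned to the other side of 50% with the scaling. At a fixed total it was 31.2% for infection in WT, 61.3% for infection in KO, 41.3% and 73.7% for genotype without and in infection, and 77.6% for the difference of responses. At a fixed total without the most abundant transcript, also chosen after seeing the data, it was 64.4% for infection in KO, 39.7% and 52.0% for genotype without and in infection, 62.9% for the difference of responses and 47.7% for genotype over both states. For infection in WT this last setting gave 53.8%, on the same side of 50% as the deposited share. Quantile normalization gave 50.2% for the difference of responses and moved genotype without infection from 69.4% to 57.4%. No paired analysis was possible because the table has 1 column per group and carries no replicate number. Leaving out libraries, the alternative limma settings and the fits on the compared groups alone could not be run for the same reason, and scaling without the haemoglobin genes, the gene lists and the site search could not be run without gene names. Depth is unknown, so what it limits was not assessed.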

Other observations

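Among the 78 transcripts at a geometric mean of 1000 FPKM or more, 2 were at least 2-fold higher and 16 at least 2-fold lower in infected than in uninfected KO spleen, while in WT spleen 3 were higher and 3 lower. Lower transcripts outnumbered higher ones in KO under each scaling tried, with 4 higher and 9 lower at a fixed total, 2 and 20 under median-ratio scaling, 5 and 7 under quantile normalization and 5 and 8 at a fixed total without the most abundant transcript. In WT the fixed total gave 3 higher and 8 lower, and the other 3 scalings 3 and 3. The difference between the genotypes was not tested.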
